A study of Mus musculus with 21 samples.

How the data were processed

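RNA from circumvallate taste buds of C57BL/6J mice was sequenced as 21 libraries, 7 in each of 3 groups per the labels. Trimmomatic, FastQC, TopHat, Bowtie2, Cufflinks and Cuffdiff and the build GRCm38.p4 are named, without versions, order or settings, per the submitters' processing notes. The authors deposited a merged transcript annotation and a table whose columns, per the file headers, are those of Cuffdiff's variance model. The deposited values are a signal, the authors' mean over libraries of size-factor-scaled fragments. It is given for fragments compatible with annotated transcripts and for total fragments of a locus, with a variance of each and a fitted variance. They are not divided by transcript length, so levels of different genes also reflect their lengths. Further upstream settings are not given in the sources used here.

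The design had been fixed before the data were examined and assumed a mean and variance per condition. That assumption did not hold, because the values of the 3 conditions were identical at all 32052 loci. Planned contrasts, gene list tests on fold changes, overlap of contrasts, leaving out libraries and regrouping of libraries therefore could not be run. The levels, the variance relative to the authors' fitted variance and its comparison with random lists were chosen after the columns had been seen. Gene lists and the 12 genes always named (such as Plcb2, Gnat3 and Lepr) had been fixed beforehand. The rest of the rule for naming genes relied on contrasts, so other genes were named after their values were seen, as abundant, variable or contrasting list members. The level of 1 list member is not reported here.

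Loci were placed and named by overlap of the merged annotation with its reference gene symbols and GENCODE M21 on GRCm38. Among 13467 detected loci, 8696 held 1 gene symbol and 4771 held several, the latter kind carrying 46.6% of compatible fragments. Detection meant a mean of at least 10 compatible fragments. A gene counted as detected where any locus that holds it reached this mean, also a locus shared with other genes. Loci listed at 0 compatible fragments numbered 12095, and 2658 of these were also at 0 in total. The sum of compatible fragments was 92.1% of the sum of total fragments. At some loci compatible exceeded total fragments, as at Gm5828 with 0.404 against 0.316. Of compatible fragments, 4.74% lay in 5 mitochondrial loci and 8.13% in the 10 most abundant loci.

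How the variance was made was read from loci with fragments in 1 library. Such loci were recognised by a variance over squared mean within a relative tolerance of 0.0001 of a value that 1 library of a set gives. Set sizes that few loci matched were dropped. By compatible fragments 1595 loci remained, at 3 values, which correspond to sets of 8, 7 and 6 libraries with a divisor of 21. Their levels were whole multiples of 1 unit per library at 469 of 474, 662 of 667 and 454 of 454 loci, within a relative tolerance of 0.0002. Units gave the size factor of each library. For 1 library of the set of 8, never seen alone, the size factor of 0.790 came from 28 loci with fragments in 2 libraries. The smallest share of a locus's fragments that its leading library can hold was taken as the variance over squared mean divided by 21.

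Excess variance was the log2 ratio of the compatible variance to the authors' fitted variance. A list's median over detected single-gene loci was placed among 10000 random lists of the same size. Each random member was drawn from the 100 detected single-gene protein-coding loci nearest in mean level. Lists with fewer than 5 such loci got no percentile. Altogether 39 lists with 1053 genes were used, 1034 genes were measured, and 26 lists had a percentile. Detection counts per list are out of all listed symbols, also those not found in the annotation. Simulated data with 21 libraries and 32052 loci tested the steps for set sizes and for libraries seen alone. They recovered 3 of 3 set sizes and 20 library units with 0 wrong. The step for a library never seen alone was not tested. Random lists in the simulation were fewer than 10000 and drawn from all detected loci. With the variance of 200 loci raised by a factor of 8, 9 of 9 lists of 20 such loci lay above the central 95%. Of 100 unchanged lists, 4 lay outside it. Simulated loci varied independently of each other, so this rate was not measured for lists of genes that vary together. Alternatives comprised other detection levels, total fragments, loci with several genes, a running median in place of the fitted variance and removal of the most uneven members. For list variability, the alternative by total fragments also used a running median in place of the fitted variance. Its members were those detected by total fragments. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.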

Results

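The series profiled RNA from circumvallate taste buds, the chemosensory organs of the trench-shaped papilla at the back of the tongue. The animals were wild-type C57BL/6J mice, an inbred laboratory strain, aged 20 to 24 weeks. GEO's labels give 21 libraries in 3 groups of 7, named Ad lib, Satiated and Hungry. The deposited expression table holds 32052 loci. For each locus it gives the authors' mean of size-factor-scaled fragments, their variance and a fitted variance. A size factor is the number each library is divided by to bring libraries of different depth to one scale. Summed over loci, the mean library held 21881979 compatible fragments, meaning fragments that match an annotated transcript, and 23769781 fragments in total. Size factors recovered from the table ran from 0.732 to 1.80, with a median of 0.991. Levels below are the authors' mean compatible fragments per library, and CV is the coefficient of variation from the authors' variance. The table holds no level per library, so no own replicate error or test accompanies a level.

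The series title poses the question of how immune genes of taste buds differ between fed and fasted mice. The table names 3 conditions by the letters C, F and H, but 0 of the 32052 loci differed between them in any of the 5 value columns. Hungry against Satiated, Hungry against Ad lib and Satiated against Ad lib therefore gave no fold change, no test and no count of changed genes. None of the levels below is a fed or a fasted level: each pools all 21 libraries. The variances had been taken within sets of libraries. Loci with fragments in 1 library were recognised by 3 values of variance over squared mean, those that sets of 8, 7 and 6 libraries give. Which set belongs to which condition was not recoverable.

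Taste cell genes were among the abundant transcripts. Rgs21, a regulator of G protein signalling found in taste cells, had 31578 fragments. Gnat3, which encodes the taste G protein gustducin, had 24576 fragments with a CV of 0.131 (chromosome 5, 17962621 to 18019834, GRCm38). Among other genes of type II cells, which sense sweet, bitter and umami compounds, Gna14 had 14587 fragments and Gnb3 had 11811. The channel gene Trpm5 had 7752 fragments with a CV of 0.107, at a locus it shares with Tssc4 (chromosome 7, 143069153 to 143094642). Plcb2, the phospholipase upstream of Trpm5, had 2833 fragments with a CV of 0.164 (chromosome 2, 118707517 to 118728438). Its total was 14992 fragments, so most fragments at Plcb2 were not compatible with an annotated transcript. Tas1r3, the shared subunit of the sweet and umami receptors, had 2686 fragments with a CV of 0.105 at a locus that also holds Dvl1 (chromosome 4, 155847402 to 155863362). The transcription factor gene Pou2f3, needed for type II cells, had 4137 fragments, and the channel subunit gene Calhm3 had 3778. Of the 23 symbols on the type II list, 22 were measured and 21 were detected, meaning a mean of at least 10 fragments at a locus that holds the gene. Such a locus can hold other genes too, and their fragments then count as well.

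Genes of type III cells, which respond to sour stimuli, were detected for 19 of 21 list members, of which 20 were measured. The proton channel gene Otop1 led them with 13734 fragments. Pkd2l1, a type III marker channel, had 4859.8 fragments with a CV of 0.196 (chromosome 19, 44147637 to 44192442). Car4, a carbonic anhydrase of type III cells, had 1089 fragments with a CV of 0.219 (chromosome 11, 84957786 to 84966044). Of the glia-like type I list, 5 of 6 genes were detected. Entpd2, the ATP-degrading enzyme of type I cells, had 13472 fragments with a CV of 0.134 at a locus shared with Npdc1 (chromosome 2, 25395874 to 25409494). The potassium channel gene Kcnj1 had 7919 fragments. Progenitor and renewal genes were detected for 22 of 23 members. Krt8, a keratin of taste bud cells, had 37058 fragments with a CV of 0.0577, and Sox2 had 11396. The basal keratin gene Krt14 had 2637 fragments with a CV of 0.987.

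**Figure D1:**
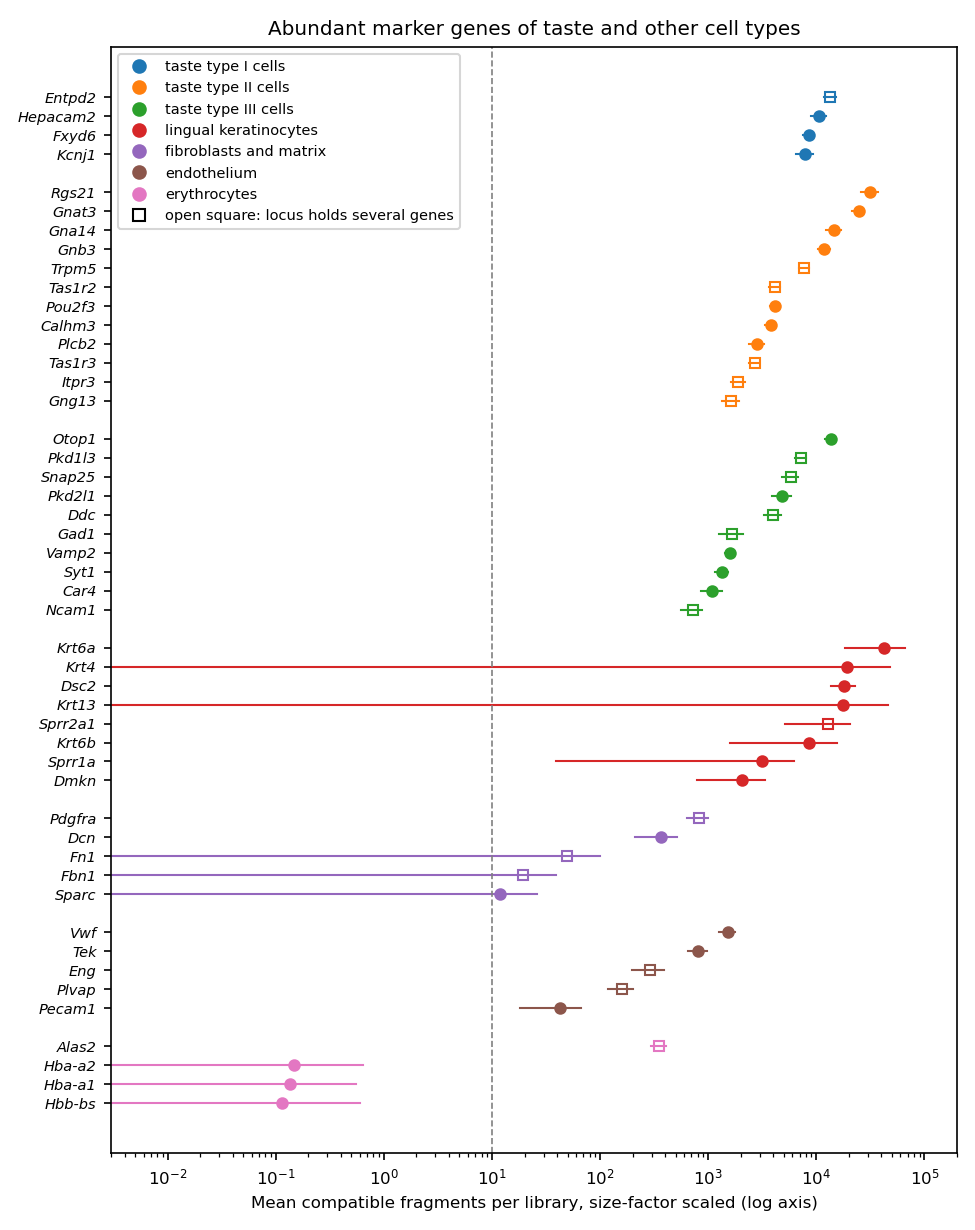
Authors' mean compatible fragments per library (horizontal log axis, size-factor scaled) for abundant members of 7 marker lists, 1 gene per line. Filled circles are loci with 1 gene symbol and open squares loci with several. Bars run 1 authors' standard deviation either side and reach the left edge where that is 0 or below, and the dashed line marks 10 fragments. Taste markers such as Gnat3 at 24576 lie far above hemoglobin genes such as Hba-a1 at 0.135.

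Bitter receptor genes were detected for 33 of 35 members. Tas2r118 was highest by compatible fragments with 2470.0, followed by Tas2r117 with 2129 and Tas2r115 with 1431. The list's median single-gene level was 295 fragments, and the median compatible share of its loci was 29.5%. Tas2r103 had 348 compatible fragments against a total of 9561, and Tas2r125 had 119.6 against 6529. Receptor order by level therefore depends on which column is read.

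**Figure D2:**
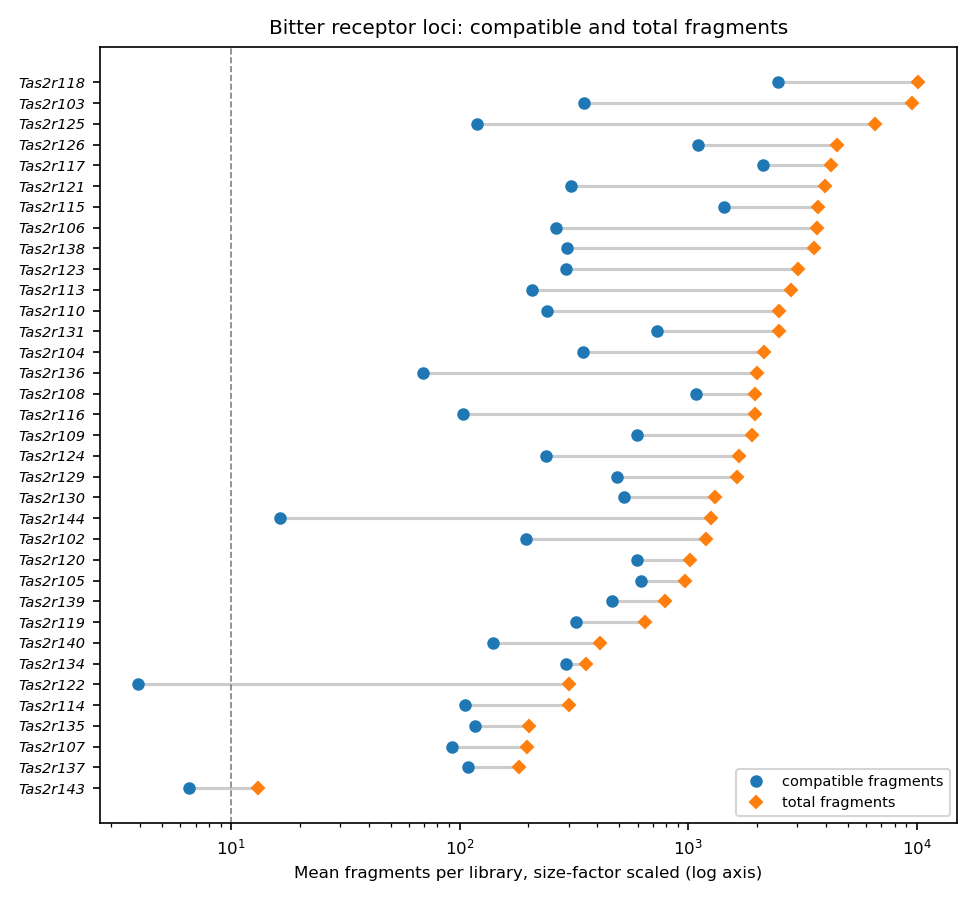
Compatible (blue circles) and total (orange diamonds) fragments per library, authors' means on a horizontal log axis, for 35 bitter receptor genes, with a dashed line at 10 fragments. Tas2r103 has 348 compatible and 9561 total fragments.

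Immune genes were widely detected. The 8 immune lists, fixed before the data were examined, hold 300 genes, of which 297 were measured and 222 were detected, 150 of them at single-gene loci. Among cytokines and chemokines, 43 of 61 were detected. Cxcl14, an epithelial chemokine, had 31405 fragments with a CV of 0.123. The alarmin gene Il33 had 2947 fragments with a CV of 0.648, Il10 had 563, Il18 had 316 and Tnf had 309.5. Among cytokine and chemokine receptors, 39 of 57 were detected. The scavenging chemokine receptor gene Ackr3 had 4503 fragments and the interferon receptor gene Ifnar1 had 1721. Toll-like and pattern receptor genes with NF-kB genes were detected for 33 of 43 members. Cd14, a co-receptor for lipopolysaccharide, had 3491 fragments, Casp1 had 1989, Tlr3 had 1727 and Tlr4 had 1113.

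Interferon response genes were detected for 42 of 45 members. Oasl2, an interferon-induced gene, had 2094 fragments with a CV of 0.914, and Ifit1 had 564 with a CV of 1.11. Antimicrobial and mucosal defence genes were detected for 21 of 34 members. The lysozyme gene Lyz2 had 33435 fragments, lactoferrin (Ltf) had 20903 with a CV of 0.608 and Wfdc18 had 14860.1. MHC class I genes were detected for 19 of 20 members, with 7 at single-gene loci, led by H2-K1 with 9557 fragments and H2-D1 with 5884. Near-identical class I genes can share fragments, so these levels are uncertain. For MHC class II, 9 of 15 were detected, and H2-Ab1 had 150.5 fragments. Complement genes were detected for 16 of 25 members, 7 at a mean of at least 50 fragments, and Clu had 2728 fragments with a CV of 1.99.

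Detection of immune cell markers depended on the cutoff. T and NK cell markers were detected for 7 of 27 members, B and plasma cell markers for 4 of 22, neutrophil markers for 4 of 16 and mast cell, basophil and eosinophil markers for 3 of 15. Macrophage and dendritic cell markers reached 16 of 30. At a mean of at least 1 fragment these 5 counts were 12, 9, 10, 6 and 27. With at least 50 fragments macrophage and dendritic cell markers numbered 8, and by total fragments B and plasma cell markers numbered 7. Gzma, a granule protease gene, had 7344 fragments while Trbc2 of the T cell receptor had 27.4. Kit had 7559 fragments while the mast cell protease gene Mcpt4 had 1.71. Lyz2 had 33435 fragments while the macrophage gene C1qa had 48.8.

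Of 46 appetite hormone and receptor genes, 18 were detected. Lepr, the leptin receptor, had 1.34 compatible and 12.7 total fragments with a CV of 1.11 (chromosome 4, 101717404 to 101815352). Adipor1, an adiponectin receptor, had 8768 fragments, Pcsk1, a prohormone convertase, had 3751 and the oxytocin receptor gene Oxtr had 1402. Glucocorticoid and fasting-induced genes were detected for 31 of 37 members. Tsc22d3 had 2437 fragments and Sgk1 had 1022. Fkbp5, a glucocorticoid-induced chaperone gene, had 149 fragments with a CV of 0.361 at a locus shared with Gm22146 (chromosome 17, 28399095 to 28517524). Pdk4, a kinase that restrains pyruvate oxidation, had 13.4 fragments with a CV of 1.59 (chromosome 6, 5483351 to 5496309).

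Fatty acid oxidation and ketogenesis genes were detected for 32 of 38 members. Cpt1a, which controls fatty acid entry into mitochondria, had 5147 fragments. Cd36, a fatty acid transporter, had 514 fragments with a CV of 0.374 (chromosome 5, 17781690 to 17888959). Lipid and sterol synthesis genes were detected for 34 of 35 members, led among single-gene loci by Hmgcs1 with 13147 fragments and with Cyp51 at 9613. For glucose metabolism, 28 of 35 genes were detected, with Pkm at 12673 fragments. All 20 circadian clock genes were detected, and Per1 had 164 fragments with a CV of 0.348 (chromosome 11, 69095217 to 69109960). Detection also covered 29 of 31 immediate early genes, 30 of 30 heat shock and unfolded protein response genes and 40 of 40 cell cycle genes. It likewise covered 46 of 47 cytosolic ribosomal protein genes, 52 of 53 nuclear respiratory chain genes and 15 of 15 mitochondrially encoded transcripts. All of these mitochondrial transcripts lay at loci with several genes.

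Detection of markers of tissue under the epithelium differed by list. Fibroblast and matrix genes were detected for 5 of 17 members, endothelial genes for 7 of 12, Schwann cell and nerve genes for 10 of 12, with 4 at single-gene loci, skeletal muscle genes for 8 of 22 and adipocyte genes for 3 of 10. At a mean of at least 1 fragment, fibroblast genes numbered 13 and muscle genes 16, and with at least 50 fragments fibroblast genes numbered 2, endothelial genes 4 and muscle genes 2. By total fragments, fibroblast genes numbered 8 and adipocyte genes 5. At single-gene loci, 2 fibroblast, 5 endothelial, 2 muscle and 2 adipocyte genes were detected by compatible fragments. Col1a2 and Col3a1, abundant collagens of connective tissue, had 5.31 and 5.32 fragments. Von Ebner and minor salivary gland genes were detected for 7 of 24 members, with 2 at single-gene loci. Among them Dmbt1 counted through a locus of 44 gene symbols with 36079 fragments. Of 8 erythrocyte symbols, 6 were measured and 1 was detected, or 2 by total fragments, and Hba-a1 had 0.135 fragments. Keratinocyte genes were detected for 23 of 27 members, with Krt6a at 41906, Krt4 at 19096 and Krt13 at 17703 fragments. All 6 sex-linked genes were detected, with Eif2s3y of the Y chromosome at 2411 fragments, Uty at 1749 and Kdm5d at 319. Only these 3 had a single-gene locus, and 4 of the 6 reached a mean of at least 50 fragments.

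Variability between libraries differed by gene list. Across the 13467 detected loci, the median CV was 0.231, with quartiles of 0.151 and 0.449. The median log2 ratio of variance to the authors' fitted variance was −0.65, and 3509 loci, 26.1%, lay above the fitted variance. Keratinocyte genes had a median log2 ratio of 3.87, against −0.77 for random lists matched on mean level, and 16 of 17 members lay above the fitted variance. Interferon response genes had a median of 1.53 against −0.55, with 30 of 32 above. Antimicrobial genes had a median of 1.81 against −0.63, with 13 of 16 above. The antimicrobial median lay 2.43 above random lists, or 1.29 without uneven members. Members S100a8, S100a9 and Ltf are also the 3 detected single-gene members of the neutrophil list. Medians of keratinocyte, interferon, antimicrobial, Toll-like and NF-kB, immediate early, cell cycle and ribosomal protein genes lay above all 10000 random lists. Clu had the largest log2 ratio among single-gene protein-coding loci of at least 100 fragments, 7.03, followed by Krt13 at 6.51 and Krt4 at 6.34. For the cornified envelope gene Lor, at 6.12, at least 54.9% of scaled fragments came from 1 library. Steady genes included Msi1 at −3.66, Ywhaz at −3.46 and Krt8 at −3.40.

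**Figure D3:**
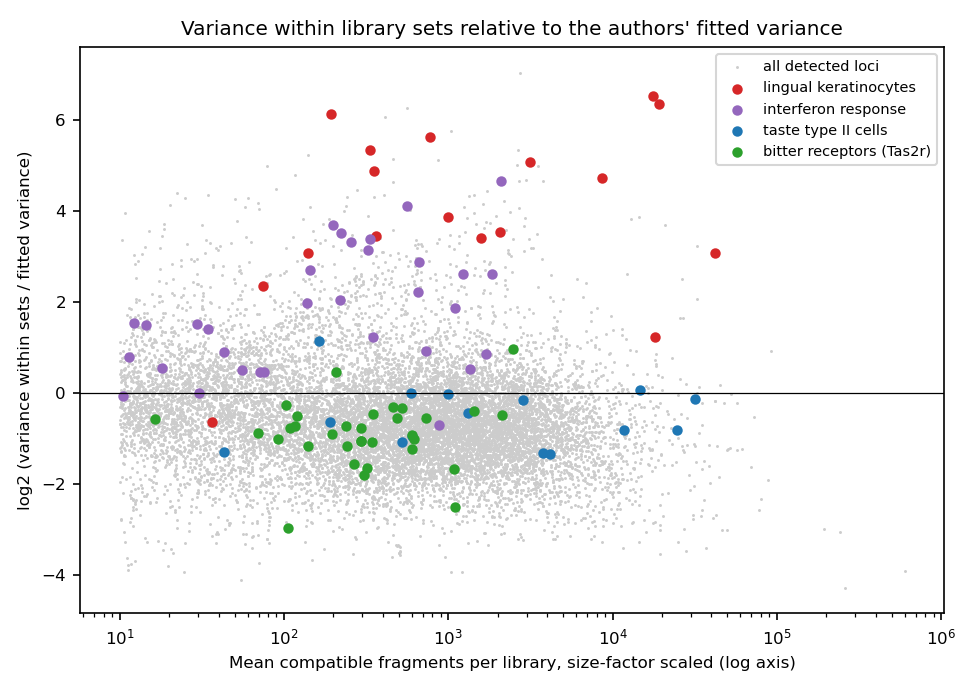
Log2 ratio of the authors' variance within library sets to their fitted variance (vertical axis) against the authors' mean compatible fragments (horizontal log axis), with 1 point per locus. Grey points are the 13467 detected loci and coloured points single-gene members of 4 lists. Keratinocyte and interferon genes lie mostly above 0, with medians of 3.87 and 1.53.

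Medians of 10 of the 26 lists with at least 5 single-gene members lay above the central 95% of random lists, and 0 lay below it. Besides keratinocyte, interferon and antimicrobial genes, ribosomal protein genes had a median log2 ratio of 0.68, cell cycle genes 0.62, macrophage and dendritic cell genes 0.42, immediate early genes 0.37, glucocorticoid and fasting-induced genes 0.33, Toll-like and NF-kB genes 0.32 and cytokines 0.12. Within the central 95% lay the taste lists, at −0.63 for type II genes, −0.88 for bitter receptors, −0.94 for type III genes and −0.09 for progenitor genes. Immune lists within it were MHC class II at 0.37, complement at 0.39, MHC class I at −0.19 and cytokine receptors at −0.56. Also inside were appetite genes at 0.17, clock genes at −0.49, sterol synthesis at −0.53, glucose metabolism at −0.58, respiratory chain at −0.65, fatty acid oxidation at −0.67, heat shock genes at −0.85 and endothelium at −0.52. The alternative by total fragments also replaced the fitted variance with a running median and chose members by total fragments. By it, bitter receptors, MHC class II and complement genes also lay above the central 95%, at percentiles of 99.8, 99.8 and 97.9. Progenitor, appetite, complement and heat shock genes did so when loci of several genes were added or uneven members removed. Respiratory chain genes fell below it, to a percentile of 0.89, with loci of several genes. Cytokines fell to a percentile of 66.6 without their most uneven members, and glucocorticoid and fasting-induced genes to 86.0 with loci of several genes. Distances above random lists fell from 0.97 to 0.41 for Toll-like and NF-kB genes with loci of several genes, from 0.99 to 0.46 for immediate early genes by total fragments and from 0.94 to 0.62 for glucocorticoid and fasting-induced genes without uneven members. These percentiles describe these libraries only, because genes vary together and lists share members.

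**Figure D4:**
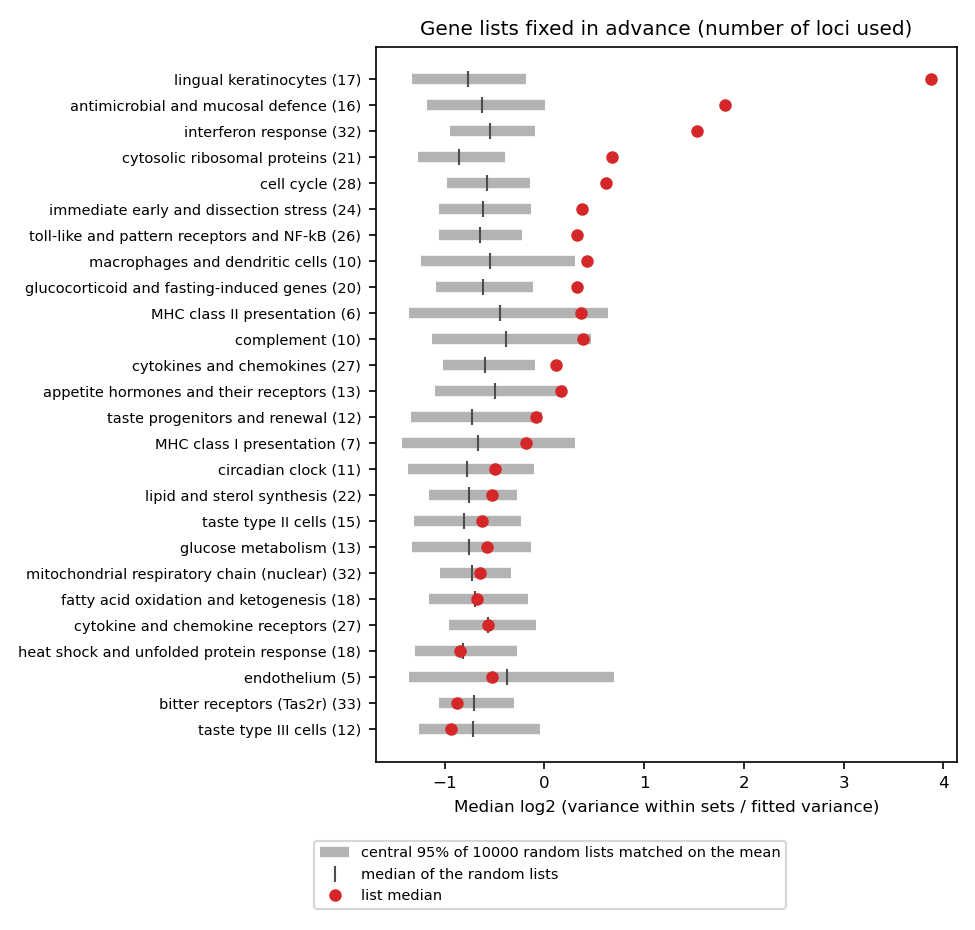
Median log2 ratio of variance within library sets to the authors' fitted variance (horizontal axis) for 26 gene lists, with the number of single-gene loci in brackets. Red points are list medians, ticks the median of 10000 random lists matched on mean level and grey bars their central 95%. Keratinocyte genes stand highest at 3.87.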

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

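The tests of library sets and of keratinocyte and interferon variability were chosen only after those results had been seen, whereas both tests of bitter receptor loci were fixed before their results were seen.

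Bitter receptor loci carried many fragments that were not compatible with their annotated transcripts, as at Tas2r103, with 9561 total fragments. A candidate explanation is that their gene models lack untranslated regions. Among other protein-coding loci, the median compatible share was 43.1 percentage points lower without untranslated regions than with them (52.6% against 95.7%). Background spread over the genome was argued against, since olfactory and vomeronasal receptor loci had 0.0109% of the other fragments per kb seen at bitter receptors. No biological explanation was tested, and 8 bitter receptors with untranslated regions still had a median compatible share of 43.5%, against 16.1% for 25 without.

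The variances behind the table came from sets of 8, 7 and 6 libraries, while the labels give 7 in each group. The loci that revealed the sets also rule out equal sets of 7, because 58.2% of them had another variance over squared mean, which is no separate test. A candidate explanation is that 1 library was entered under another condition, and the sets hold 21 libraries in all, as that explanation and others need. It cannot be told apart from other regroupings, because which set is which condition is unknown.

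Keratinocyte and interferon genes varied more within sets than the authors' fitted variance. Mean level was argued against as the cause, since the lower of both percentiles among matched random lists was 100. That comparison is the one reported above and no separate test. Dilution alone, by tissue that carries none of these transcripts, was argued against as the source of this difference, since it lowers all other genes alike. The median CV was 0.173 over 24 type II and type III genes with a mean of at least 100 (quartiles 0.134 and 0.218). Against that, lower quartiles were 0.721 for 15 keratinocyte genes and 0.448 for 20 interferon genes, fewer than the members used above. That contrast is part of the flagged pattern, so it is no separate test. Size factors can remove a change shared by all genes, so whether dilution occurred stays open. Low taste gene CVs do not argue against a small share of tissue that carries the transcripts. Connective tissue as a carrier of these transcripts was argued against too by the median of its 17 genes. That median was 1.36% of the smaller of the median standard deviations of both lists (upper quartile 3.69%), with Col1a2 at 5.31 fragments. Of the 17, 12 were not detected, and the highest at a single-gene locus had 364 fragments, above that standard deviation of 324. Vessels and nerve that carry interferon transcripts remain open. Of 3 lists of connective tissue, vessels and nerve, 0 lay above the central 95%, but only 1 had enough members to be placed. A varying share of keratinocytes also may play a part, and stays open without values per library. The median CV was 1.05 over 15 keratinocyte genes with a mean of at least 100 (0.255 to 3.40). Feeding group cannot explain differences within a correctly labelled group, but with the sets unmatched to labels it was not tested. Feeding state of single animals within a group was not tested either.

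A few libraries lay far from the others of their set, in 4 of 9 tests. Chance marks about 1 in 20 groups of normally distributed values, but no rate was measured for such counts, and the 9 tests share libraries. In the set of 6, 1 library was the sole source of 193 loci by compatible fragments (30 to 79 in the others) and of 624 loci by total fragments (17 to 74). In the set of 8, 1 library had a size factor of 1.80 (0.790 to 1.14 in the others), and 1 library was the sole source of 143 loci by total fragments (0 to 49).

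Total fragments, which the levels do not use, were many at some loci where compatible fragments were few, and their source was not tested. At least 100 total fragments were present at 203 loci listed at 0 compatible. Tlr1, a Toll-like receptor gene, had 7199 total fragments, of which under 10 were compatible, and Tlr13 had 1129 total. Plcb2 had 14992 total fragments.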

How the results depend on the processing

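All alternatives given here were chosen after seeing the data, because those planned beforehand needed values that differ between conditions and were not run. No paired analysis was possible because the columns carry no replicate and the conditions hold identical values. Leaving out each library, other splits of the libraries and other scalings, pseudocounts and variance models for contrasts were not possible for the same reason.

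Of 239 alternatives, 197 stayed within the spread or ratio set for them and 42 moved. The ratio was narrower for levels of genes than for counts of genes or loci. Altogether 0 turned a list outside the central 95% of random lists to the other side of their median. For genes detected per list, 101 of 117 stayed, and for levels of the genes fixed in advance, 8 of 12 stayed between compatible and total fragments, and Plcb2, Gnat3, Tas1r3 and Lepr moved. Detected loci numbered 13467 in the main count and 8696 with exactly 1 gene, which is fewer by construction. For list variability relative to random lists, 82 of 103 stayed. Keratinocyte genes lay 4.64 above random lists, 4.17 with loci of several genes and 4.26 with members of variance over squared mean under 1. Interferon genes lay 2.08 above, and 1.85 both against a running median and by total fragments. The alternative by total fragments also used a running median in place of the fitted variance, so these are not separate checks. Antimicrobial genes lay 2.43 above, 2.13 by total fragments and 1.29 without uneven members. Among lists inside the central 95%, 6 moved by more than the spread of random lists to the other side of their median. By total fragments with its running median, bitter receptors went from −0.17 (33 members) to 0.52 (35 members). Endothelium went from −0.15 (5 members) to 0.40 (7 members) in the same way. Against a running median alone, with compatible fragments, bitter receptors lay at −0.22 and endothelium at 0.08. With loci of several genes, type III genes went from −0.23 to 0.36, heat shock genes from −0.03 to 0.52 and respiratory chain genes from 0.08 to −0.35. Cytokine receptors went from 0.003 to −0.22 without uneven members. The causes were not tested. Depth limits genes near 10 fragments, and a gene listed at 0 is not shown to be absent.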

Other observations

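Every gene in this part was chosen after its values were seen. Several genes outside the gene lists were abundant or uneven. Anxa1, an anti-inflammatory annexin, had 91692 fragments with a CV of 0.358. Msln (mesothelin) had 50297 fragments, the endopeptidase gene Mme 47934 and the adhesion gene Epcam 40934. The chemokine gene Ppbp had 1039.9 fragments with a CV of 1.59. Among list members, the secretory transcription factor gene Xbp1 had 39392 fragments, the chemokine gene Cxcl5 had 871 with a CV of 1.35, and S100a9 had 117 fragments with a CV of 2.59, and at least 32.0% of them came from 1 library.

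Some total fragment levels far exceeded the compatible level outside the taste genes. Camk2b had 14578 total against 475 compatible fragments, and Gnai1 had 13750.0 total against 423. Of 11327 loci with at least 100 total fragments, 562 were under 10% compatible.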
